A study of Equus caballus with 20 samples.

How the data were processed

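Small RNA was sequenced from extracellular vesicles of follicular fluid of mares (horse), in 20 libraries from 5 stages of follicle growth with 4 libraries each. Per the labels' protocols, vesicles were pelleted by ultracentrifugation, and libraries were made with the TruSeq Small RNA kit. Tools named in the submitters' processing notes are bcl2fastq, Bowtie2 2.2.2 and DESeq2, with the horse genome build EquCab3.0, without a role or an order. Neither the miRNA annotation nor the counting settings are given in the sources used here. No reference genome was used here, so miRNAs are given by name without coordinates.

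The deposited values, named CPM by the authors, are a scaled read signal rather than CPM on plain library totals. Columns summed to between 774632 and 1778185, while CPM on plain totals sum to the same total in every library. CPM with a normalization factor per library need not do so, and such CPM are not excluded. Of the values, 100% were whole multiples, within a tolerance of 1e-06, of the smallest value above 0 in the column. Whole reads were recovered by dividing by that value, which was worth between 7.04 and 36.5 in a library. How the factor per library was set is not given in the sources used here. The unit had been planned as CPM, and the planned test on the log2 scale was kept because it fits a scaled signal as well. Values are called scaled reads, or CPM where a setting was defined on them.

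The table held 686 miRNA names, of which 325 were above 0 in any library and 361 were listed at 0 in all. Names carry the horse prefix eca- in the table, left out here, and none stands in more than 1 line. A total of 264 miRNAs with at least 10 scaled reads in at least 4 libraries were tested. Libraries held between 27131 and 110130 recovered reads, 1457859 in all. Reads carry no molecular identifiers, so intervals (95%) and floors (3 reads over a group) cover counting error only. Precision was low: over the 264 tested miRNAs, the median half-width of the 95% interval of a log2 fold change was 2.69 for a pair of stages and 0.60 for the trend per stage step.

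Tests were run with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), with all 20 libraries in 1 fit and a mean per stage. Contrasts were an F test over the 5 stages, a linear trend over the stage order with scores from -2 to 2, and 6 comparisons of a pair of stages. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, so those of scarce miRNAs depend on the pseudocount and, with libraries at 0, can be smaller or larger than the ratio of the means. Where a group held 0 reads, the fold is a bound against the floor of 3 reads over the group, and where it held 1 to 3 reads, a depth-adjusted ratio of reads is given with its counting interval. A count such as 4 of 4 gives the libraries of a stage that lay beyond all 4 libraries of the other. The labels do not tie libraries to mares, of which the design text names 19, so p-values measure the spread between these samples. With 20 libraries, some would share a mare, within or across stages, and the tests treat all of them as independent. The labels give no batch or date.

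There were 24 lists of miRNAs fixed beforehand: LH-responsive granulosa, miR-183 cluster, miR-17-92 cluster and paralogs, let-7 family, miR-200 family, DLK1-DIO3 imprinted cluster, X-linked miR-424 cluster, X-linked miR-506 family, gonadal somatic, miR-23-27-24 clusters, miR-221-222, miR-99-100-125-10 group, miR-30 family, miR-29 family, miR-26 and miR-148 group, miR-181 family, hypoxia, and markers of red blood cells, leukocytes, endothelium and platelets, liver and plasma, muscle and stroma, stratified epithelium, and neural and endocrine tissue. Members were matched by name, with all arms, and miR-223 is in the lists of leukocytes and of endothelium and platelets. The 18 lists with at least 3 measured members were tested with limma's camera, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Library measures (detected miRNAs, share of the 10 most abundant miRNAs, reads, sum of values) were compared by exact two-sided permutation tests over 70 arrangements, whose smallest p is 0.0286, adjusted over 6 comparisons.

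The miRNAs named in the text followed a rule: of those past the threshold in a comparison, the 12 largest rises and the 12 largest falls (for the F test the 15 smallest p); where fewer than 5 passed, the 8 smallest p, said not to pass; up to 4 members of a list, those past the threshold by smallest p and then the most abundant; and the 10 most abundant miRNAs. The groups, this rule, the lists, the tests and the alternatives in the next sentence were chosen before the data were examined. Alternatives chosen beforehand were pseudocounts of 0.5 and 10, no filter, a mean of at least 100, quantile normalization, rescaling by the median of ratios over the 114 miRNAs above 0 in every library, no intensity trend, array weights, the replicate number as a block, only the compared pair of stages in the fit, a detection minimum of 1 or 100 scaled reads, the 5 or 20 most abundant miRNAs, and leaving out each library. Alternatives added after seeing the data were reads brought to the same total in every library without the deposited scale factor (equal library totals), leaving out both libraries under 40000 reads, edgeR 4.0.16 with the deposited scaling or TMM, DESeq2 1.42.0 on recovered reads, detection at thinned reads, and the lists under other scalings and without each library.

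The test was checked on simulated data drawn from the real means and spreads, with 42 of 264 miRNAs changed in each of 10 simulations. For postdeviation against predeviation it found 7.86% of the miRNAs changed 2-fold, 29.3% of those changed 4-fold and 50.7% of those changed 8-fold, and 2.10% of its calls were false. Among the 58 miRNAs with a mean of at least 1000 these shares were 25%, 75.9% and 93.1%. For impending ovulation against preovulatory it found 1.43%, 20% and 33.6%, with 7.92% false calls. A planted list of 6 members was found in 9 of 10 simulations of postdeviation against predeviation, and an unchanged list in 0. Means and spreads carry no correlation between miRNAs, so this check does not cover lists whose members vary together. In the real data no list passed with an estimated correlation in any comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

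Reads of near-identical miRNAs could be split between them by the counting, so values of miR-192 and miR-215, miR-10a and miR-10b, miR-27a and miR-27b, miR-34b and miR-34c, miR-199a and miR-199b, miR-200b and miR-200c, miR-99a and miR-100, and members of the let-7 family are uncertain to that extent.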

Results

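Follicular fluid of mares was collected by aspiration through the vaginal wall at 5 stages of growth of a follicular wave, and the miRNAs of its extracellular vesicles, membrane-bound particles released by cells, were sequenced. Follicles of 18 to 20 mm were assigned to predeviation, those of 22 to 25 mm to deviation, when the future dominant follicle outgrows the others, those of 26 to 29 mm to postdeviation and those of 30 to 35 mm to preovulatory. The last stage, impending ovulation, has no diameter in the labels. Each stage held 4 libraries. Recovered reads per library ranged from 41360 to 110130 at predeviation, 71805 to 94917 at deviation, 55118 to 89957 at postdeviation, 27131 to 110062 at preovulatory and 29862 to 88126 at impending ovulation. The shallowest libraries were preovulatory 3 with 27131 reads and impending ovulation 2 with 29862. The design asks which vesicle miRNAs differ as a follicle passes from predeviation to ovulation. No pair of replicates held the same reads within counting noise (smallest chi-square per degree of freedom 15.6), so none was treated as a duplicate of another. This does not show that the libraries are from separate mares.

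A few miRNAs made up most of the vesicle cargo. MiR-148a held 22.8% ± 7.51 (SD, n = 20) of the values, miR-21, a miRNA raised by luteinizing hormone (LH) in granulosa cells, 11.1% ± 7.73, miR-99a 6.70% ± 2.88 and miR-192 6.52% ± 3.08. They were followed by miR-10b (5.36% ± 1.46), miR-10a (4.79% ± 1.44), miR-423-5p (4.19% ± 1.18), miR-215 (2.49% ± 1.19), miR-143 (2.22% ± 1.86) and miR-486-5p (1.91% ± 1.34). This order is over all 20 libraries and differs between stages: miR-192 averaged more than miR-21 at postdeviation (92666 against 72390 scaled reads) and at impending ovulation (81230 against 77134). Predeviation library 4 stood apart, with 828709 scaled reads of miR-148a, 46.6% of its sum of 1778185. The numbers of miRNAs past the threshold (adjusted p under 0.05) were 13 in the limma F test over the 5 stages, 16 between postdeviation and predeviation, 15 between impending ovulation and predeviation and 15 in the trend over the stage order. Between consecutive stages they were 1, 0, 0 and 0.

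Predeviation and postdeviation are the stages before and after a dominant follicle is selected, and 16 miRNAs differed between them. Vesicles after selection held more miR-192 and miR-215, which share a seed sequence and are abundant in liver, gut and kidney. MiR-192 averaged 29890 ± 16911 scaled reads at predeviation and 92666 ± 7439 at postdeviation (SD, n = 4), a 3.49-fold rise (log2 1.8 ± 0.31 SE, limma adjusted p = 0.000601, higher in 4 of 4 libraries). MiR-215 rose 3.69-fold, from 12011 ± 6413 to 38287 ± 3861 (log2 1.88 ± 0.35, limma adjusted p = 0.00111, 4 of 4). MiR-22 rose 3.68-fold, from 6838 ± 956 to 25804 ± 7756 (log2 1.88 ± 0.31, limma adjusted p = 0.000601, 4 of 4), and brain-enriched miR-128 rose 2.39-fold, from 8814 ± 4320 to 19638 ± 3242 (limma adjusted p = 0.0110, 4 of 4). The same libraries held less of miR-34b, miR-34c and miR-96, of the epithelial miR-200c and of miR-146b-5p, a miRNA of NF-kB feedback in immune cells.

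Of the 16 miRNAs, 10 rose. MiR-483, encoded in an intron of IGF2, rose from 42.5 ± 47.5 to 963 ± 445, a fitted 54.9-fold (log2 5.78 ± 0.99, limma adjusted p = 0.000601, 4 of 4). The size of this rise is uncertain, with a log2 change of 4.66 at a pseudocount of 10, 4.41 with edgeR, and 4.45, 6.40 and 6.68 without predeviation 3, 4 and 1. Within the imprinted DLK1-DIO3 cluster, miR-485-3p had 110 reads against 2, a depth-adjusted ratio of 50.8 (counting interval 13.7 to 424, limma adjusted p = 0.000858, 4 of 4; fitted log2 5.96, but 5.26 without predeviation 2 or 3, 6.59 without predeviation 1, 6.71 without predeviation 4, 6.80 with quantile normalization and 4.06 at a pseudocount of 10), and miR-323-3p rose 5.21-fold to 1087 ± 303 (log2 2.38 ± 0.57, limma adjusted p = 0.0110, 4 of 4). MiR-615-3p, from the HOXC5 locus, rose 3.81-fold to 1261 ± 441 (log2 1.93 ± 0.47, limma adjusted p = 0.0110, 4 of 4). MiR-92a of the growth-promoting miR-17-92 cluster rose 2.26-fold, from 3036 ± 943 to 6627 ± 152 (log2 1.17 ± 0.27, limma adjusted p = 0.00733, 4 of 4). MiR-27a rose 1.97-fold (log2 0.98 ± 0.27, limma adjusted p = 0.0224), with 3 of 4 postdeviation libraries above all of predeviation.

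The 6 miRNAs that fell included miR-34b and miR-34c, p53-induced miRNAs of multiciliated epithelia and germ cells. MiR-34c had 2 reads at postdeviation against 1007, a 546-fold lower level (counting interval 151 to 4512, limma adjusted p = 0.00168, lower in 4 of 4). The size of this fall is uncertain, since predeviation 2 held 8303 scaled reads against a mean of 970 ± 485 in the other 3, and the fitted log2 change of -8.65 became -7.84 without it, -9.41 without postdeviation 4 and -6.65 at a pseudocount of 10. MiR-34b-3p had 0 against 55 reads, at least 19.9-fold lower (limma adjusted p = 0.0135, 4 of 4), and miR-34b-5p 0 against 49, at least 17.7-fold lower (limma adjusted p = 0.0119, 4 of 4; edgeR 0.0646 and DESeq2 0.0921 did not call it), both against a floor of 3 reads over the group. MiR-96 of the miR-183 cluster had 1 read against 86, 93.2-fold lower (16.3 to 3723, limma adjusted p = 0.0110, 4 of 4). MiR-200c fell 5.17-fold, from 1419 ± 901 to 272 ± 170 (log2 -2.37 ± 0.60, limma adjusted p = 0.0119, 4 of 4). MiR-146b-5p fell 3.52-fold, from 2884 ± 611 to 936 ± 454 (log2 -1.81 ± 0.46, limma adjusted p = 0.0119, 4 of 4).

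The calls of miR-483, miR-485-3p, miR-22, miR-192, miR-215, miR-92a and miR-34c, were kept without any of the 20 libraries. Without predeviation 2, 7 miRNAs passed (6 higher, 1 lower) and the other 9 of the 16 had limma adjusted p from 0.0599 to 0.0846, while 21 passed without predeviation 4. MiR-200c and miR-146b-5p were also lost without postdeviation 1 (adjusted p 0.0616 to 0.0710), and miR-27a without postdeviation 2 (0.0711), postdeviation 4 (0.0650) or predeviation 1 (0.0924). With each library brought to the same total instead of the deposited scale, 21 passed (16 higher, 5 lower), compared with 10 higher and 6 lower in the main test. Some calls were lost under other alternatives. MiR-34b-5p was lost with edgeR under both scalings and with DESeq2 (adjusted p 0.0646 to 0.0921), and miR-146b-5p with quantile normalization (0.0503), equal library totals (0.0537) and only these 2 stages in the fit (0.0761). MiR-27a was kept in 10 of 15 alternatives and lost with quantile normalization, without the intensity trend, with only these 2 stages and with edgeR under both scalings (0.0667 to 0.140). MiR-128 was lost with only these 2 stages (0.0761) and without the intensity trend (0.0565), and miR-200c with only these 2 stages (0.0515).

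Grouped by list, the liver and plasma markers stood higher at postdeviation (camera adjusted p = 0.00389). It had an adjusted p = 0.304 with an estimated correlation, and fry gave 0.0227. Of the 4 measured members miR-192 and miR-215 passed, also when adjusted over the list alone. The liver miRNA miR-122 was at 11485 ± 6697 against 6774 ± 6393 (log2 0.97 ± 0.48, limma adjusted p = 0.285). MiR-194, transcribed together with miR-192 and miR-215 in other mammals, was at 455 ± 104 against 549 ± 155 (log2 -0.25 ± 0.70, limma adjusted p = 0.878), a sign that turned with quantile normalization (0.00) and with libraries brought to equal totals (0.17). The list passed without any single library (camera adjusted p 0.000346 to 0.0108). The plot of the liver and plasma markers gives their values per library.

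**Figure D1:**
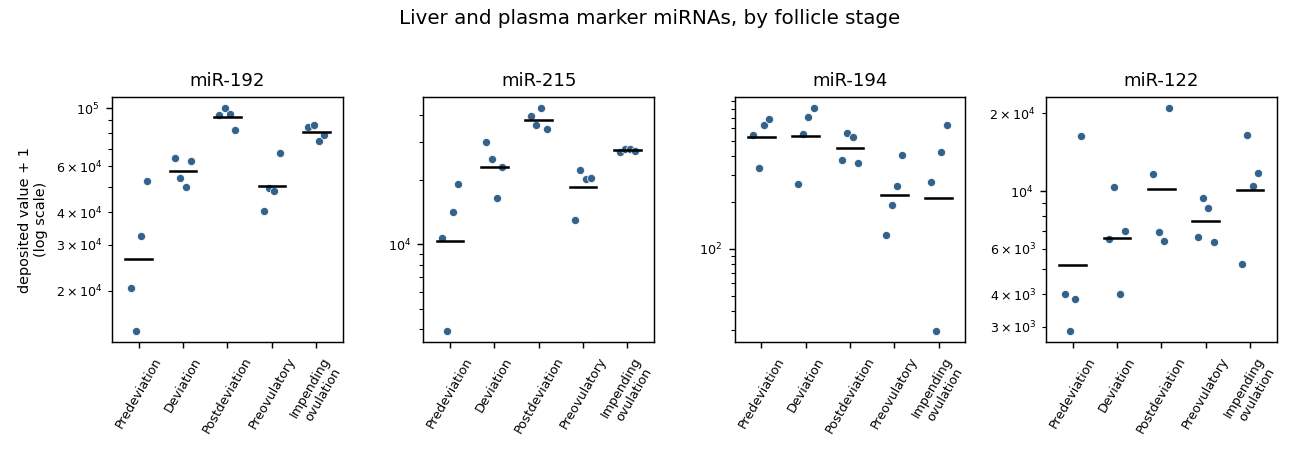
Scaled reads per library (log axis) of miR-192, miR-215, miR-194 and miR-122 over the 5 stages, with points for libraries and black bars for geometric means of value + 1. MiR-192 averages 29890 at predeviation and 92666 at postdeviation, while miR-194 averages 549 and 455.

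DLK1-DIO3 members, an imprinted cluster expressed in development, were higher as a list by camera (adjusted p = 0.0265), but not with an estimated correlation (adjusted p = 0.489) or by fry (0.254). Of 28 measured members 20 had a higher fitted value, and 2 rose over all miRNAs and 2 adjusted over the list alone, miR-323-3p and miR-485-3p. Examples that did not pass were miR-543 (log2 1.20, limma adjusted p = 0.172), miR-409-3p (1.0, 0.322) and miR-127 (0.42, 0.541). The list was lost without predeviation 1 (camera adjusted p = 0.0551), predeviation 2 (0.239), postdeviation 2 (0.0940) or postdeviation 3 (0.155).

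The gonadal somatic list missed the threshold (camera adjusted p = 0.0543, fry 0.0481). Besides miRNAs of granulosa, Sertoli and related cells, it holds miR-34b, miR-34c and miR-449a. Of its 7 members 3 were lower over all miRNAs, miR-34c and both arms of miR-34b. Adjusted over the list alone, 4 were lower and 1 higher. The list therefore does not show a fall of granulosa or Sertoli miRNAs as such. Its miR-449a, of the miR-34 family, had 1 read against 27 (29.3-fold lower, 4.82 to 1198, limma adjusted p = 0.0956). In the miR-200 family (camera adjusted p = 0.0957) miR-200c fell and miR-200b was at 1118 ± 677 against 3185 ± 1029 (log2 -1.60 ± 0.49, limma adjusted p = 0.0573); both passed when adjusted over the list alone. In the miR-183 cluster (0.193) miR-96 fell, while miR-182 (log2 -0.97) and miR-183 (-0.34) did not pass. Among blood markers, the leukocyte list (0.245) held the fall of miR-146b-5p in 1 of 8 members, and miR-155 had a log2 change of -1.02 (limma adjusted p = 0.434). The red blood cell list (0.455) had miR-451 at -0.70 (limma adjusted p = 0.669) and miR-486-3p at -2.54 (0.157, passing over the list alone), and the endothelium and platelet list (0.455) miR-126-3p at -1.0 (0.279).

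No other list passed. Camera adjusted p was 0.245 for the let-7 family, 0.286 for the miR-26 and miR-148 group, 0.387 for neural and endocrine markers, of which miR-128 rose, and 0.455 for the X-linked miR-424 cluster, the miR-99-100-125-10 group and the miR-30 family. It was 0.515 for the miR-23-27-24 clusters, of which miR-27a rose, 0.567 for the miR-17-92 cluster and paralogs, of which miR-92a rose, 0.567 for the miR-29 family and 0.882 for muscle and stroma markers, where miR-143 had a log2 change of -1.30 (limma adjusted p = 0.285) and miR-206 of 2.34 (0.112). Lists with fewer than 3 measured members had no camera test. Of these, miR-21 (log2 -1.53, limma adjusted p = 0.279) and miR-132 (2 against 17 reads, 9.21-fold lower, 2.19 to 82.2, adjusted p = 0.274) of the LH-responsive list were lower only when adjusted over the list alone. The miR-221-222 pair, the miR-181 family, miR-205 and miR-31 of stratified epithelium and miR-514 of the X-linked miR-506 family had 0 members past the threshold, and the hypoxia list had 0 measured members.

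Impending ovulation was compared with predeviation as the ends of the series. Of the 10 miRNAs that rose by postdeviation, 9 were also higher at impending ovulation: miR-192 was at 81230 ± 5258 (3.06-fold, log2 1.61 ± 0.31, limma adjusted p = 0.00264, higher in 4 of 4), miR-22 at 19755 ± 3707 (2.88-fold, log2 1.52 ± 0.31, adjusted p = 0.00455, 4 of 4) and miR-92a at 8537 ± 1744 (2.86-fold, log2 1.52 ± 0.27, adjusted p = 0.00212, 4 of 4). The skeletal-muscle miRNA miR-206 rose 10.9-fold, from 339 ± 345 to 3532 ± 3494 (log2 3.45 ± 0.82, limma adjusted p = 0.0144, 4 of 4). MiR-99a, among the most abundant miRNAs of the vesicles, fell 2.40-fold from 89667 ± 17411 to 38119 ± 11764 (log2 -1.26 ± 0.37, limma adjusted p = 0.0466, lower in 4 of 4), a call that only 5 of 15 alternatives kept.

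Of the 15 miRNAs, 12 rose. MiR-483 rose by a fitted 35.2-fold (log2 5.14 ± 0.99, limma adjusted p = 0.00264, 4 of 4), miR-323-3p 6.05-fold (log2 2.60 ± 0.57, adjusted p = 0.00706, 4 of 4), miR-197 5.39-fold (log2 2.43 ± 0.66, adjusted p = 0.0260, 4 of 4) and miR-615-3p 3.26-fold (log2 1.70 ± 0.47, adjusted p = 0.0287, 4 of 4). MiR-215 rose 2.66-fold (log2 1.41 ± 0.35, limma adjusted p = 0.0193, 4 of 4) and miR-128 2.36-fold (log2 1.24 ± 0.31, adjusted p = 0.0184, 3 of 4). MiR-758, another DLK1-DIO3 member, had 27 reads against 0, at least 8.47-fold higher (limma adjusted p = 0.0229, 4 of 4), and miR-485-3p 18 against 2, a ratio of 8.47 (2.03 to 75.3, adjusted p = 0.0260, 4 of 4), which edgeR and DESeq2 did not call. Besides miR-99a, miR-23b fell by a fitted 18.5-fold (log2 -4.21 ± 1.12, limma adjusted p = 0.0260, lower in 4 of 4) and miR-146b-5p 3.11-fold (log2 -1.64 ± 0.46, adjusted p = 0.0287, 4 of 4).

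No list passed (lowest camera adjusted p 0.0719, liver and plasma markers). Adjusted over the list alone, the calls added to those over all miRNAs were miR-27a higher and miR-27b lower, miR-99b lower, miR-148a lower, miR-126-5p lower, and miR-143 and miR-145, of smooth muscle, lower. Over all miRNAs, miR-148a had a log2 change of -1.09 ± 0.33 (limma adjusted p = 0.0543), which became 0.22 with quantile normalization, miR-143 of -1.93 (0.0814) and miR-145 of -2.30 (0.0856). MiR-34c had a log2 change of -4.0 (limma adjusted p = 0.198) and miR-9a of 3.83 ± 1.97 (0.304).

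Fitted sizes moved with single libraries. The log2 change of miR-483 was 3.80, 5.76 and 6.04 without predeviation 3, 4 and 1, and 3.67 with edgeR. That of miR-23b was -3.62, -2.89 and -5.09 without predeviation 2, impending ovulation 2 and impending ovulation 4, that of miR-206 was 4.06 and 2.86 without predeviation 4 and impending ovulation 2, that of miR-197 was 1.84 without predeviation 3, and that of miR-485-3p, 4.02 in the fit, was 3.33 without predeviation 2 or 3, 4.66 and 4.77 without predeviation 1 and 4, 4.76 with quantile normalization and 2.26 at a pseudocount of 10. The calls leaned on single libraries as well. MiR-192, miR-22, miR-323-3p, miR-483 and miR-92a were kept without any of the 20. The number past the threshold was 5 without predeviation 2 (lost calls at limma adjusted p 0.0663 to 0.116), 6 without impending ovulation 1 (0.0544 to 0.0962), 7 without impending ovulation 2 (0.0584 to 0.195) and 21 without predeviation 4. Without predeviation 3, 11 passed and miR-485-3p, miR-197, miR-615-3p, miR-128, miR-23b and miR-99a were lost (0.0503 to 0.112). MiR-197, miR-146b-5p and miR-99a were lost without impending ovulation 3 (0.0562 to 0.0826), and miR-146b-5p without predeviation 1 (0.0751). MiR-99a passed only without predeviation 1, deviation 2, 3 or 4, or preovulatory 1 or 3, and had adjusted p from 0.0524 to 0.195 without any of the other 14. Without both libraries under 40000 reads 7 passed, all higher, and with only these 2 stages in the fit 4 did. MiR-99a was lost with no filter, quantile normalization, median-of-ratios rescaling, equal library totals, array weights, the replicate block, edgeR with TMM, only these 2 stages, no intensity trend and both shallow libraries left out (adjusted p 0.0516 to 0.294). MiR-485-3p was lost at a pseudocount of 10, with only these 2 stages, without both shallow libraries, with edgeR under both scalings and with DESeq2 (0.0806 to 0.185). MiR-146b-5p was lost with quantile normalization (0.0575), equal library totals (0.124), no intensity trend (0.0787) and both shallow libraries left out (0.0817). MiR-215 was kept in 11 of 15 alternatives, miR-128 and miR-615-3p in 12, miR-197, miR-206 and miR-23b in 13, and miR-22 and miR-92a in all 15. The main split of 12 higher and 3 lower was 20 and 1 with equal library totals and 11 and 1 with quantile normalization.

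Both comparisons use the predeviation libraries. Together they shared 10 calls, 9 higher (miR-128, miR-192, miR-215, miR-22, miR-323-3p, miR-483, miR-485-3p, miR-615-3p, miR-92a) and 1 lower (miR-146b-5p). At impending ovulation, alternatives other than a left-out library lost miR-485-3p in 6 cases, miR-215 and miR-146b-5p in 4 each and miR-128 and miR-615-3p in 3 each. They lost miR-192, miR-323-3p and miR-483 in 1 each. At postdeviation they lost miR-146b-5p in 3 and miR-128 in 2. Over the 264 miRNAs, which are not independent replicates, the fold changes had r = 0.642 and a covariance of 2.08. Independent lists of these lengths would share 0.455 higher and 0.0682 lower calls. That expectation leaves out the shared controls. In 100 simulations of unchanged groups against shared controls, r was 0.497, the covariance 0.877 and the mean number of shared calls 0.010 (at most 1). With no change in any group hardly any miRNA is called. A number of shared calls near 0 is then given by construction and is no measure of a common change. With the predeviation libraries split 2 and 2 between the comparisons, in 6 ways, r was 0.279 to 0.426, the covariance 1.16 to 1.59 and 0 to 5 calls were shared.

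Over the whole stage order, miR-92a rose, from 3036 ± 943 at predeviation over 4816 ± 578, 6627 ± 152 and 8030 ± 1088 to 8537 ± 1744 at impending ovulation (log2 0.38 ± 0.06 per stage step, limma adjusted p = 0.000462). Of the 15 miRNAs with a trend 12 rose and 3 fell. MiR-483 rose by 1.20 ± 0.22 per step (limma adjusted p = 0.00229), miR-206 by 0.87 ± 0.18 (0.00599), miR-485-3p by 0.89 ± 0.24 (0.0242), miR-204b by 0.68 ± 0.17 (0.0143) and miR-323-3p by 0.63 ± 0.13 (0.00425). MiR-197 rose by 0.58 ± 0.15 (limma adjusted p = 0.0143), miR-615-3p by 0.37 ± 0.11 (0.0354), miR-22 by 0.31 ± 0.07 (0.00774), miR-192 by 0.30 ± 0.07 (0.00855) and miR-128 by 0.27 ± 0.07 (0.0158). MiR-758 rose with reads of 0, 1, 2, 17 and 27 over the stages (limma adjusted p = 0.00774). The vesicle-abundant miR-148a fell by 0.30 ± 0.07 (limma adjusted p = 0.0136), from 409806 ± 279306 to 169839 ± 29512 scaled reads, with a slope of 0.02 under quantile normalization. The first of these means rests on predeviation 4, without which it was 270172 ± 5592, and the call was also lost with equal library totals (0.0598), without the intensity trend (0.0595) and without both shallow libraries (0.0836). MiR-146b-5p fell by 0.42 ± 0.10 (0.0136; 0.0614 at equal library totals) and miR-34b-5p by 1.24 ± 0.36 (0.0408), a slope between -1.58 and -0.62 over the alternatives and left-out libraries.

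No list passed in the trend (lowest camera adjusted p 0.150, shared by neural and endocrine markers, the gonadal somatic list and the miR-17-92 cluster and paralogs). Adjusted over the list alone, miR-370 and miR-155 were also higher, as were miR-215 and miR-9a, and miR-23b, miR-27b, miR-221, miR-222, miR-99a, miR-486-3p, miR-194, miR-143 and miR-145 were also lower. Their limma adjusted p over all miRNAs ranged from 0.0581 for miR-99a (log2 -0.27 per step) to 0.181 for miR-222 (-0.25). The calls of miR-146b-5p, miR-192, miR-197, miR-206, miR-22, miR-323-3p, miR-483, miR-758 and miR-92a were kept without any of the 20 libraries. Without impending ovulation 2, 9 passed and miR-485-3p, miR-204b, miR-615-3p, miR-128, miR-34b-5p and miR-148a were lost (limma adjusted p 0.0544 to 0.138). Without predeviation 4 and without impending ovulation 4, 25 passed each. Without impending ovulation 1 (0.0510 to 0.10) or predeviation 2 (0.0698 to 0.0994), 11 passed and miR-485-3p, miR-615-3p, miR-128 and miR-34b-5p were lost. MiR-485-3p and miR-615-3p were lost without predeviation 3 (0.0650), and miR-615-3p without preovulatory 3 (0.0543). MiR-34b-5p passed only without predeviation 1 or 4, deviation 1 or 2, postdeviation 2 or impending ovulation 4 (otherwise 0.0524 to 0.138). It was lost in 6 of 13 alternatives, among them edgeR (0.139) and DESeq2 (0.228). MiR-485-3p and miR-615-3p were lost in 4 of 14 alternatives each (0.0526 to 0.136), miR-128 in 3 (0.0516 to 0.0836) and miR-204b in 1 (0.115). The split of 12 higher and 3 lower was 23 and 1 with equal library totals.

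The F test, which asks whether any stage differs, passed 13 miRNAs. MiR-192, miR-22, miR-483, miR-485-3p and miR-92a had a limma adjusted p of 0.00369, miR-215 and miR-323-3p 0.0161, miR-204b 0.0200, miR-34c 0.0257, miR-200c and miR-206 0.0365, and miR-128 and miR-146b-5p 0.0438. Levels of miR-34c ran from 2803 ± 3688 at predeviation over 495 ± 469, 7.13 ± 8.76 and 57.1 ± 35.3 to 566 ± 841 at impending ovulation. MiR-200c followed with 1419 ± 901, 641 ± 237, 272 ± 170, 309 ± 156 and 1172 ± 840. MiR-485-3p was at 8.45 ± 9.91, 183 ± 189, 344 ± 308, 252 ± 122 and 73.7 ± 34.5. Without predeviation 1 or deviation 4, 8 passed, without predeviation 2, 7, and without impending ovulation 4, 20, of which 8, 8, 7 and 13 were among the 13. The plot of selected miRNAs gives the values per library.

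**Figure D2:**
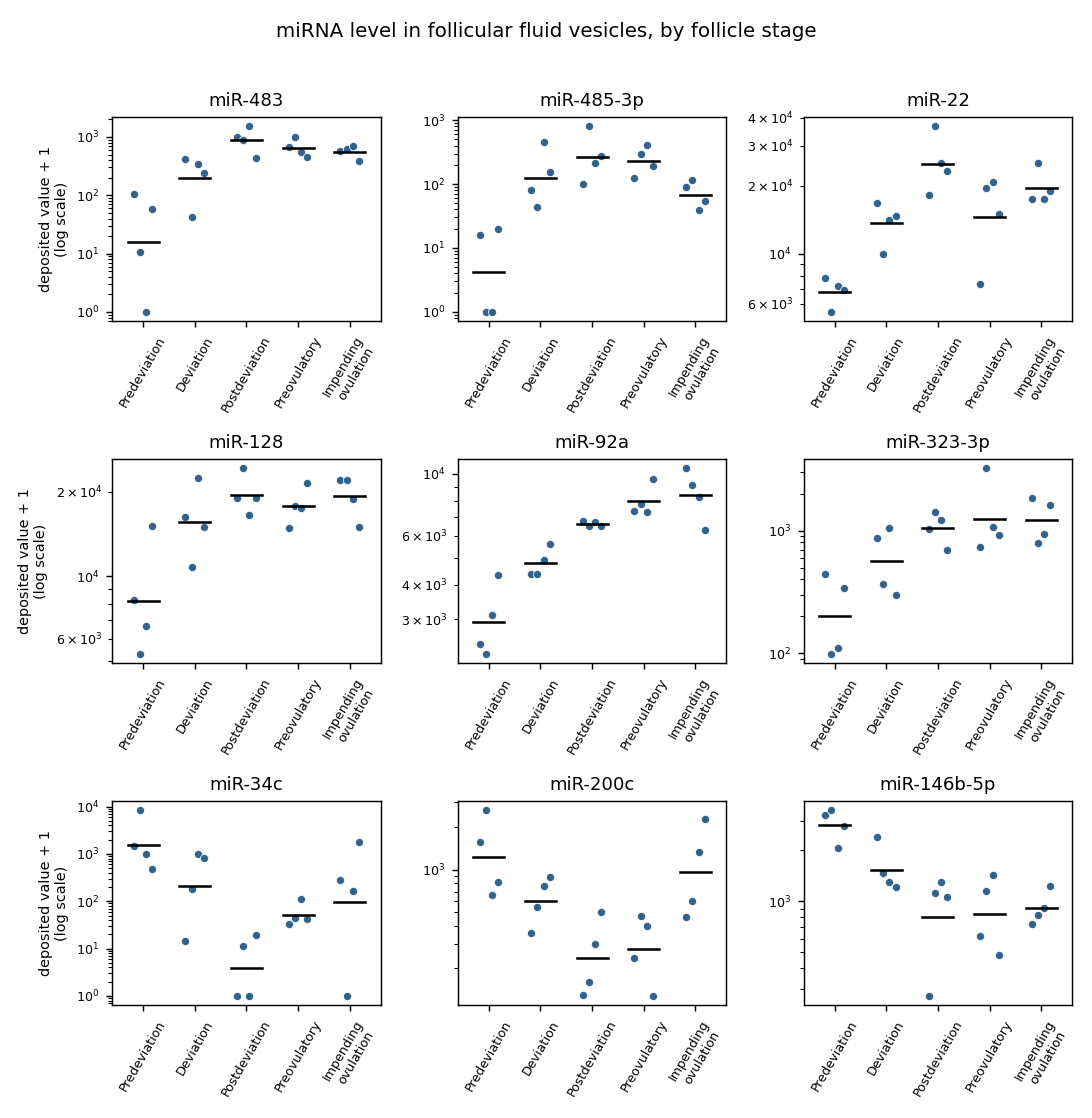
Scaled reads per library (log axis) of miR-483, miR-485-3p, miR-22, miR-128, miR-92a, miR-323-3p, miR-34c, miR-200c and miR-146b-5p over the 5 stages, with points for libraries and black bars for geometric means of value + 1. MiR-92a averages 3036 at predeviation and 8537 at impending ovulation, and miR-34c 2803 at predeviation and 7.13 at postdeviation.

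From predeviation to deviation, when growth of the dominant follicle starts to part from that of the others, 1 miRNA passed. The imprinted miR-485-3p had 51 reads at deviation against 2, a ratio of 22.4 (5.89 to 190, limma adjusted p = 0.0395, higher in 4 of 4). Several miRNAs that rose by postdeviation had intermediate values at deviation without passing: miR-192 averaged 57726 ± 6969 (log2 1.12 ± 0.31, limma adjusted p = 0.105), miR-215 23578 ± 5625 (1.15, 0.150), miR-22 13851 ± 2811 (1.0 ± 0.31, 0.153), miR-27a 12916 ± 2417 (0.90, 0.144) and miR-483 262 ± 165 (3.62 ± 0.99, 0.105). MiR-1180 was at 15.8 ± 31.5 against 162 ± 79.5 (fitted log2 -5.70 ± 1.54 with 3 libraries at 0, limma adjusted p = 0.105), and miR-128 at 16083 ± 4737 (0.94, 0.183). At an unadjusted p under 0.05 there were 21 miRNAs.

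The call of miR-485-3p was lost without 12 of the 20 libraries: predeviation 2 (limma adjusted p = 0.221), deviation 4 (0.170), deviation 3 (0.148), predeviation 3 (0.106), deviation 1 (0.0804), postdeviation 3 (0.0624), preovulatory 4 (0.0619), postdeviation 4 (0.0611), preovulatory 2 (0.0608), impending ovulation 1 (0.0546), preovulatory 3 (0.0543) and preovulatory 1 (0.0522). It was also lost with edgeR (0.0994), which called 0, with edgeR and TMM (0.0633), at a pseudocount of 10, with the replicate block (0.106) and with only these 2 stages in the fit (0.473). Its size is uncertain as well: the fitted log2 change of 4.89 became 4.20 without predeviation 2 or 3, 5.53 and 5.64 without predeviation 1 and 4, 4.27 without deviation 3, 5.81 with quantile normalization and 3.07 at a pseudocount of 10. Without predeviation 4, 5 miRNAs passed, and without predeviation 1 or deviation 2, 2 did.

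As lists, liver and plasma markers were higher at deviation (camera adjusted p = 0.0250; adjusted p = 0.539 with an estimated correlation; fry 0.354), with 4 of 4 members at a higher fitted value, 0 past the threshold over all miRNAs and miR-192 and miR-215 higher when adjusted over the list alone. The DLK1-DIO3 cluster was higher (camera adjusted p = 0.0425; adjusted p = 0.539 with an estimated correlation; fry 0.510), with 20 of 28 members at a higher fitted value and miR-485-3p passing, and miR-543 at a log2 change of 1.01 (limma adjusted p = 0.558). The gonadal somatic list was lower (camera adjusted p = 0.0494; adjusted p = 0.539 with an estimated correlation; fry 0.354), with 0 of 7 members at a higher value, 0 past the threshold in either adjustment, miR-34c at a log2 change of -2.86 (limma adjusted p = 0.760) and miR-449a at 2 against 27 reads (15.4-fold lower, 3.87 to 134, 0.400). Adjusted over the list alone, miR-27a and miR-128 were also higher. The liver and plasma call was lost without predeviation 1 (0.0693), predeviation 2 (0.106) or deviation 2 (0.117) and with quantile normalization (0.0716), and that of the DLK1-DIO3 cluster without predeviation 1 (0.0693), predeviation 2 (0.336), predeviation 3 (0.0536), deviation 1 (0.0713) or deviation 2 (0.117). The gonadal somatic call held only without deviation 3 or 4 or impending ovulation 2, 3 or 4, and was at 0.0501 to 0.156 without any of the other 15.

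Between deviation and postdeviation, as the dominant follicle grows past selection, vesicles differed by less than the test could call. No miRNA passed in limma, edgeR called 0 with the deposited scaling and 0 with TMM, DESeq2 called 3, and 16 had an unadjusted p under 0.05 in limma. The smallest p-values belonged to miR-204b, at 400 ± 254 against 53.7 ± 39.9 (log2 2.75 ± 0.76, limma adjusted p = 0.324), and miR-34c, with 2 reads against 144 (68.5-fold lower, 18.6 to 571, 0.324). They were followed by miR-22 (log2 0.88 ± 0.31), miR-361-5p (3 against 14 reads, 4.44-fold lower, 1.24 to 24.1), miR-96 (1 against 16 reads, 15.2-fold lower, 2.36 to 638) and miR-383 (3 against 0 reads), all at limma adjusted p = 0.641, and by miR-206 (2.01) and miR-486-3p (-2.35), both at 0.711. MiR-192 had a log2 change of 0.69 (limma adjusted p = 0.711) and miR-215 of 0.73 (0.737). No list passed with camera (lowest adjusted p 0.146, liver and plasma markers), and with fry 0 lists passed. Adjusted over the list alone, miR-96 and miR-34c were lower and miR-383 higher. Without postdeviation 2 and without impending ovulation 2, 1 miRNA passed each.

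From postdeviation to preovulatory, the liver and plasma markers were lower and the let-7 family, miRNAs of differentiated cells, was higher by camera (adjusted p = 0.278 and adjusted p = 0.371 with an estimated correlation), and no miRNA passed alone. MiR-192 averaged 51373 ± 11485 against 92666 ± 7439 (log2 -0.87 ± 0.31) and miR-215 18944 ± 4062 against 38287 ± 3861 (-1.04 ± 0.35), both with all 4 preovulatory libraries below all 4 of postdeviation (limma adjusted p = 0.337 for both). MiR-101 (log2 1.5 ± 0.48), miR-98 of the let-7 family (1.79 ± 0.63), miR-148b-3p (0.92 ± 0.32), miR-490-3p (71 against 0 reads, at least 18.4-fold higher), miR-361-5p (22 against 3 reads, 5.72-fold, 1.72 to 29.8) and miR-493b (2 against 14 reads, 8.98-fold lower, 2.06 to 81.4) had the same limma adjusted p of 0.337. The reads of miR-490-3p came nearly all from preovulatory 1 and 4. In limma 28 miRNAs had an unadjusted p under 0.05, and edgeR with either scaling and DESeq2 called 0.

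The liver and plasma list was lower (camera adjusted p = 0.00307; adjusted p = 0.278 with an estimated correlation; fry 0.0898), with 4 of 4 members at a lower value, 0 past the threshold over all miRNAs and miR-192 and miR-215 lower when adjusted over the list alone. MiR-122 was at 7766 ± 1468 against 11485 ± 6697 (log2 -0.41, limma adjusted p = 0.775) and miR-194 at 243 ± 119 against 455 ± 104 (-1.01, 0.577). This call held without any library (0.000452 to 0.0118). The let-7 family was higher (camera adjusted p = 0.0263; adjusted p = 0.371 with an estimated correlation; fry 0.0351), with 6 of 7 members at a higher value and 0 past the threshold in either adjustment; let-7a was at 10614 ± 919 against 7697 ± 2236 (log2 0.51, limma adjusted p = 0.470), let-7f at 9950 ± 2531 against 5718 ± 2241 (0.85, 0.430) and let-7g at 17989 ± 4260 against 11370 ± 3925 (0.69, 0.430). The DLK1-DIO3 cluster was lower (camera adjusted p = 0.0263; adjusted p = 0.595 with an estimated correlation; fry 0.667), with 9 of 28 members at a higher value and 0 past the threshold in either adjustment, miR-409-3p at a log2 change of -0.92 (limma adjusted p = 0.470) and miR-543 at -0.74 (0.532). Adjusted over the list alone, miR-148b-3p was also higher. The let-7 call was lost without postdeviation 1 (0.05004), postdeviation 3 (0.172), preovulatory 2 (0.176) or preovulatory 3 (0.146), after median-of-ratios rescaling (0.0618) and without both libraries under 40000 reads (0.161), and the DLK1-DIO3 call without postdeviation 2 (0.0919), postdeviation 3 (0.210) or preovulatory 3 (0.244) and without both libraries under 40000 reads (0.287).

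From preovulatory to impending ovulation, the list of endothelium and platelet markers was lower by camera, and the miR-183 cluster and the miR-200 family, miRNAs of epithelial identity, were higher by camera. With an estimated correlation none of these lists passed (lowest adjusted p = 0.159 with an estimated correlation). No miRNA passed in limma. MiR-182 was at 1136 ± 774 against 248 ± 135 (log2 2.05 ± 0.59), miR-340-5p at 183 ± 145 against 891 ± 263 (-2.51 ± 0.64), miR-23b at 37.1 ± 42.0 against 259 ± 110 (-3.96 ± 1.12) and miR-126-5p at 4 against 33 reads (fitted -5.33 ± 1.53 with 3 libraries at 0), all at limma adjusted p = 0.134. MiR-199a-5p (log2 -1.65 ± 0.52) and miR-101 (-1.5 ± 0.48) were at 0.192, and miR-200c (1.8 ± 0.60) and miR-99b (-1.36) at 0.194. In limma 24 had an unadjusted p under 0.05, edgeR called 0 with the deposited scaling and 0 with TMM, and DESeq2 called 3. Without predeviation 4, 1 passed, and without impending ovulation 4, 3 did.

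The endothelium and platelet list was lower (camera adjusted p = 0.0192; adjusted p = 0.159 with an estimated correlation; fry 0.00994), with 0 of 6 members at a higher value and miR-126-5p, miR-199a-3p and miR-199a-5p lower when adjusted over the list alone. MiR-126-3p, abundant in endothelium, was at 2155 ± 769 against 3423 ± 2279 (log2 -0.55, limma adjusted p = 0.743). The miR-183 cluster was higher (camera adjusted p = 0.0192; adjusted p = 0.457 with an estimated correlation; fry 0.518), with 3 of 3 members at a higher value, miR-182 higher when adjusted over the list alone and miR-183 at 1965 ± 423 against 960 ± 298 (log2 1.05, limma adjusted p = 0.464). The miR-200 family was higher (camera adjusted p = 0.0192; adjusted p = 0.514 with an estimated correlation; fry 0.549), with 4 of 5 members at a higher value and miR-200b (log2 1.48 ± 0.49) and miR-200c higher when adjusted over the list alone. Over all miRNAs, 0 members of these lists passed, and miR-23b and miR-99b were lower when adjusted over their own lists alone. The endothelium and platelet call was lost without preovulatory 3 (0.0839), impending ovulation 1 (0.0801) or impending ovulation 4 (0.152) and without both libraries under 40000 reads (0.0554), that of the miR-183 cluster without impending ovulation 4 (0.152), and that of the miR-200 family without preovulatory 1 (0.216), preovulatory 4 (0.126), impending ovulation 3 (0.110) or impending ovulation 4 (0.186).

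The share of the 10 most abundant miRNAs was 77.6% ± 2.62 at predeviation, 73.8% ± 1.76 at deviation, 69.9% ± 1.92 at postdeviation, 65.4% ± 3.15 at preovulatory and 66.4% ± 2.35 at impending ovulation (SD, n = 4). Postdeviation and impending ovulation each had an exact permutation p of 0.0286 against predeviation, the smallest these tests can give, and an adjusted p of 0.0857. The sum of values per library gave the same p in both comparisons. Detected miRNAs, with at least 10 scaled reads, numbered 207.75 ± 11.7, 215.25 ± 13.0, 202 ± 10.1, 208.75 ± 27.4 and 200.5 ± 24.2 over the stages, with an adjusted exact permutation p of 0.686 in all 6 comparisons. A single read reached this minimum in all libraries but predeviation 2 and preovulatory 1 and 4. Reads per library did not differ beyond their spread (adjusted exact permutation p 0.789 to 0.943).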

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

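The test on equal library totals was chosen only after the results were seen, while for the 16 miRNAs at thinned depth or without the most abundant miRNAs, and for other splits, the tests were set before their results were seen. A library far from the other 3 of its stage was found in 30 of 340 groups of 4 libraries, by the gap to the nearest library relative to the range. For normally distributed values chance gives this in about 1 in 20 groups, 17 here. Where the other 3 libraries were at 0, any read was flagged, as for miR-1180 in deviation 3 and miR-96 in postdeviation 1. The number of 30 is therefore not shown to exceed chance.

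Predeviation 4 stood far above the other predeviation libraries, with 828709 scaled reads of miR-148a against at most 276040, a sum of values of 1778185 against at most 1136926 and 4892 scaled reads of miR-127 against at most 1979. Predeviation 3 stood apart with 11380 of miR-27a, 55.0 of miR-204b, 27.5 of miR-126-5p and 0 of miR-493b, and predeviation 1 with 14.7 of miR-490-3p. At deviation, library 3 had 63.1 of miR-1180 where the others had 0 and 15.8 of miR-361-5p, library 1 had 13.1 of miR-758, library 2 had 0 of miR-493b and library 4 had 94917 reads. At postdeviation, library 1 had 273 scaled reads of miR-146b-5p and 14.4 of miR-96, library 2 had 0 of miR-383 and 89957 reads, library 3 had 32891 of miR-10a, and library 4 had 2133 of miR-200b. Preovulatory 1 had 7034 of miR-27a, preovulatory 3 had 1898 of miR-615-3p, and preovulatory 4 had 35.2 of miR-383 and 14.1 of miR-493b. At impending ovulation, library 1 had 1342 of miR-183, library 3 had 0 of miR-34b-3p and 12.7 of miR-493b, and library 4 had 1094 of miR-145, 117 of miR-34b-5p, 42.5 of miR-126-5p and 10.6 of miR-490-3p. The values given here for miR-490-3p, miR-361-5p, miR-758 and miR-96 were each worth 1 recovered read. So were those of miR-126-5p in predeviation 3 and of miR-493b in impending ovulation 3.

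Other splits of the same libraries were counted for each comparison, each split once and the real one included. For postdeviation against predeviation, only the real split, 1 of 35, gave as many as the 16 miRNAs (highest other 7). This is the smallest share that 35 splits can give, and it was not adjusted over the comparisons, so it does not exclude chance. For the 2 lists, 8 of 35 splits gave as many (highest other 3). For the F test (13 miRNAs, highest other 2) and the trend (15, highest other 12), only the real grouping, 1 of 100, gave as many. This is again the smallest share that these draws can give, without adjustment. A count of 0 is reached by every split by definition, which says nothing about chance; this holds for the 0 lists of the trend (100 of 100, highest other 5). Chance cannot be excluded for the 15 miRNAs of impending ovulation against predeviation, where 2 of 35 splits gave as many and the highest other, 17, parted predeviation 1, 2 and 3 with impending ovulation 4 from the rest. Its count of 0 lists is again reached by all 35 splits (highest other 2).

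Between consecutive stages chance cannot be excluded for the counts above 0. For deviation against predeviation 3 of 35 splits gave as many as the 1 miRNA (highest other 3) and 4 of 35 as many as the 3 lists (highest other 3). For postdeviation against deviation the counts of 0 miRNAs (highest other 0) and 0 lists (highest other 3) are reached by all 35 by definition and say nothing about chance. For preovulatory against postdeviation 7 of 35 gave as many as the 3 lists (highest other 4), and the 0 miRNAs allow no such statement. The highest other split for miRNAs called 21 and put postdeviation 1 and 3 with preovulatory 1 and 4, which points to a structure of the samples. For impending ovulation against preovulatory 9 of 35 gave as many as the 3 lists (highest other 5), and the 0 miRNAs again allow none. The highest other split for miRNAs called 16 and put preovulatory 1 and 4 with impending ovulation 3 and 4, which also points to a structure of the samples.

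The 16 miRNAs that differed between postdeviation and predeviation were weighed against technical explanations. The scale factor per library as the whole cause is argued against, since 15 of the 16 passed with the same direction at equal library totals. A difference in reads per library is argued against, since with all libraries thinned to 27131 reads a median of 13.5 of the 16 passed over 10 draws (10 to 15). A share taken by miR-148a and miR-21 is argued against, since 16 passed with both taken out of the totals. A candidate explanation that stays open is a difference of the follicle stages themselves, which the labels do not separate from differences between mares or collection days.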

How the results depend on the processing

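Equal library totals, both libraries under 40000 reads left out, edgeR, DESeq2, detection at thinned reads and the lists under other scalings or without a library were tests chosen after the data were seen. Each called miRNA was counted once per alternative or left-out library. The direction and the side of the threshold were kept in 530 such cases and lost in 28 for postdeviation against predeviation, 439 and 85 for impending ovulation against predeviation, 456 and 50 for the trend (besides the sign of miR-148a) and 18 and 17 for deviation against predeviation. Leaving out a library of an uncompared stage cannot move the fold change of a pair of stages, so those cases say little about stability. The cause of the moves was not tested unless stated. For the F test (13 miRNAs) 2 passed without the intensity trend, 45 with array weights, 21 with edgeR, 27 with edgeR and TMM, and 7 to 20 without single libraries. For deviation against predeviation (1) it was 0 with a pseudocount of 10, 11 with array weights, 0 with only these stages in the fit, 7 at equal library totals, 2 without both shallow libraries, 0 with edgeR, 0 with edgeR and TMM, 2 with DESeq2, and 0 to 5 without single libraries. For postdeviation against deviation (0) it was 2 with array weights, 1 without both shallow libraries, 3 with DESeq2 and 0 to 1 without single libraries. For impending ovulation against preovulatory (0) it was 7 with array weights, 3 with DESeq2 and 0 to 3 without single libraries. Preovulatory against postdeviation gave 0 under every alternative run. For postdeviation against predeviation (16) it was 7 to 21 without single libraries, and within 1.5 times the main count under the other alternatives, with 14 by edgeR, 14 by edgeR with TMM and 18 by DESeq2 on the recovered reads. For impending ovulation against predeviation (15) it was 4 with only these stages in the fit, 7 without both shallow libraries, 17 with edgeR, 16 with edgeR and TMM, 24 with DESeq2 and 5 to 21 without single libraries. For the trend (15) it was 31 with array weights, 24 at equal library totals, 9 without both shallow libraries, 13 with edgeR, 16 with edgeR and TMM, 28 with DESeq2 and 9 to 25 without single libraries.

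The sign of miR-194 between postdeviation and predeviation (-0.25) turned to 0.0035 with quantile normalization and 0.17 at equal library totals, and that of miR-451 (-0.70) turned to 0.077 without predeviation 2, while its log2 change was -1.06 without predeviation 4 and lowest, -1.33, with edgeR and TMM. The sign of miR-148a turned with quantile normalization, to 0.22 between impending ovulation and predeviation and to 0.022 in the trend. By construction, that scaling gives the most abundant miRNA of each library the same value. This was miR-148a except in predeviation 3 and preovulatory 3, where it was miR-21. Lists past the threshold with an estimated correlation were 0 in deviation against predeviation (main 3), preovulatory against postdeviation (3), impending ovulation against preovulatory (3) and postdeviation against predeviation (2). With fry they were 0, 1, 1 and 2 in these, and in the last of them the DLK1-DIO3 cluster was lost and the gonadal somatic list passed instead. At equal library totals 1 list passed for postdeviation against deviation (0) and 1 for impending ovulation against predeviation (0), as did 1 for the latter after median-of-ratios rescaling. Without both shallow libraries 5 passed for impending ovulation against preovulatory, while endothelium and platelet markers were lost (camera adjusted p = 0.0554). Without single libraries lists numbered 0 to 3, 0 to 1, 1 to 3 and 0 to 5 in the consecutive comparisons, 1 to 4 for postdeviation and 0 to 1 for impending ovulation against predeviation. The direction of the called lists did not turn under a scaling, but quantile normalization ended the call of liver and plasma markers in deviation against predeviation (0.0716), and median-of-ratios rescaling that of the let-7 family in preovulatory against postdeviation (0.0618).

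Scalings moved the median log2 fold change of all miRNAs, and changes are relative to that. Quantile normalization moved it by 0.15 for deviation against predeviation, -0.33 for preovulatory against postdeviation, 0.27 for impending ovulation against preovulatory, 0.29 for postdeviation and 0.19 for impending ovulation against predeviation. Equal library totals moved it by 0.14 for deviation against predeviation, 0.17 for postdeviation against deviation, 0.34 for postdeviation and 0.39 for impending ovulation against predeviation and 0.11 for the trend. Median-of-ratios rescaling moved it by 0.11 for postdeviation against deviation and 0.13 for postdeviation against predeviation.

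The difference in detected miRNAs between deviation and predeviation (7.5) was 0 at a minimum of 1, -4 at a minimum of 100 and -0.64 with thinned reads. A single read fell short of the main minimum of 10 in predeviation 2 (worth 9.79) and preovulatory 1 (8.17) and 4 (7.04) only. Predeviation 2 had 201 detected miRNAs at a minimum of 10 and 231 at 1. The other libraries of both stages had equal numbers at these minima, so the difference of 7.5 came from predeviation 2. Without single libraries the difference in detected miRNAs ranged from -2.33 to 16.3 for preovulatory against postdeviation (6.75), from -17.8 to 1.58 for impending ovulation against preovulatory (-8.25) and from -16.75 to 2.58 for impending ovulation against predeviation (-7.25). The difference in the share of the 10 most abundant miRNAs between impending ovulation and preovulatory (1.04 percentage points) ranged from -0.468 to 2.14. No name stood in more than 1 line of the table, so keeping every line changed nothing. Depth limits the scarce miRNAs: 1 read was worth up to 36.5 scaled reads.

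With the replicate number as a block, 9 miRNAs passed in the F test, 0 in deviation against predeviation, 0 in the other consecutive comparisons, 16 and 14 in postdeviation and impending ovulation against predeviation and 15 in the trend, and the lists past the threshold numbered 3, 0, 3, 3, 2, 0 and 0. Same-numbered libraries of different stages had a mean correlation of deviations of -0.0368 over 40 pairs, against 0.0124 over 120 pairs with other numbers, and 4 of 20 libraries correlated best with their own number. The numbers are not taken as a pairing.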

Other observations

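The liver and plasma test, the correlations of miR-9a with other miRNAs and those over 12 libraries were tests chosen only after the results were seen. Some miRNAs, picked after their values were seen, varied widely between vesicles of the same stage, among them miR-7, miR-124 and miR-9a of the neural and endocrine list. This does not hold for the whole list: miR-128 was at 16083 ± 4737 at deviation and 19638 ± 3242 at postdeviation. Preovulatory 1 and 4 held 32836 and 22635 scaled reads of miR-7, against 1146 and 1387 in preovulatory 2 and 3. The neuronal miR-124 was at 139 and 91.5 in preovulatory 1 and 4 and listed at 0 in the other 2, and miR-490-3p was at 294 and 239 against 14.7 and 0. Impending ovulation 3 had 33479 scaled reads of miR-7 and impending ovulation 1 had 1268. MiR-9a averaged 962 ± 832, 286 ± 441, 4842 ± 5458, 6994 ± 8083 and 10439 ± 12036 over the stages (SD, n = 4), and its trend did not pass (log2 1.27 ± 0.44 per step, limma adjusted p = 0.0917).

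Of miRNAs linked to LH and to immune cells, miR-21 averaged 194892 ± 113251 at predeviation, 135756 ± 84582 at deviation, 72390 ± 58308 at postdeviation, 95901 ± 88593 at preovulatory and 77134 ± 51213 at impending ovulation. MiR-132 had 17, 10, 2, 29 and 31 reads over the stages. MiR-155, induced in activated leukocytes, was at 362 ± 118 at predeviation and 1319 ± 842 at impending ovulation (log2 1.58, limma adjusted p = 0.219), while miR-146b-5p, of the same list, fell. Smooth-muscle miR-143 was at 44643 ± 34097 at predeviation and 16396 ± 22042 at impending ovulation.

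MiR-192 and miR-215 rose from predeviation to postdeviation, and miR-194 did not pass the test. A candidate explanation is vesicles of liver or plasma, whose list, fixed beforehand, held 4 measured miRNAs that no other list holds; how many of them the follicle itself expresses was not measured here. This cannot be told apart from a difference of the stages: the log2 ratio of miR-192 to miR-194 went from 5.64 ± 0.45 to 7.69 ± 0.25 (SD, n = 4), a change of 2.05 (exact permutation p = 0.0286, the smallest this test can give, adjusted p = 0.171 over 24 tests, higher in 4 of 4), which restates the pattern it was chosen from and misses the threshold after adjustment. Too few reads for miR-194 to be measured are argued against, since the libraries of both stages held at least 20 reads of it (at most 53). Its change was imprecise, with an SE larger than the fitted change, so a rise of miR-194 is not excluded. Levels of the other members decide nothing either: the liver miRNA miR-122 averaged 6774 and 11485, and the log2 ratio of miR-192 to miR-122 changed by 0.83 (exact permutation p = 0.2, adjusted p = 0.48).

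MiR-9a was high where miR-21 was low within stages, and postdeviation and preovulatory libraries fell apart into 2 sets. In 4 libraries miR-9a was at 9383 to 16242 and miR-21 at 24882 to 30344. In the other 4 miR-9a was at 21.2 to 256 and miR-21 at 88832 to 216068. The first 4 were postdeviation 1 and 3 and preovulatory 1 and 4, the split of these stages that called 21 miRNAs. It was picked here from the values, so no p-value is given for it. Over all 20 libraries within stages r was -0.693 (permutation p = 0.00693, adjusted p = 0.0375 over 8 relations; rho = -0.726, p = 0.00451, adjusted p = 0.0277; r = -0.825 without the 2 libraries farthest from the median), a value that includes that split and was picked because it was among the most negative of all tested miRNAs, with miR-26a at r = -0.716, so these p-values do not cover the choice of miR-21, and over the 12 libraries of the other stages the relation was not established (r = -0.501, permutation p = 0.148; rho = -0.580, permutation p = 0.0822). A difference in reads per library is argued against, since miR-9a followed it with r = 0.206 over within-stage deviations of 20 libraries (permutation p = 0.404, adjusted p = 0.462 over 8 relations; rho = 0.146, p = 0.552, adjusted p = 0.567; r = 0.353 without the 2 libraries farthest from the median), and the share taken by miR-21 is argued against, since the within-stage SD of miR-9a was 26.7 times the SD that this share gives to all others. Cells or vesicles of neural or endocrine origin may contribute and cannot be told apart from other sources, since 1 of the 3 other markers had r under 0.3 (miR-128, -0.0739), and the other 2, miR-124 (0.421) and miR-7 (0.386), lay between that limit and the r of at least 0.5 that this source would need, although miR-7 was at 0.283 and miR-124 at 0.417 without the 2 libraries farthest from the median, and over the 12 libraries of the other 3 stages none of the 3 followed miR-9a (r = -0.0862 for miR-124, 0.0484 for miR-7 and 0.0842 for miR-128). No biological explanation from the stages was tested, since the pattern lies within them.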
